A study of Bos taurus with 11 samples.

How the data were processed

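Endometrial RNA of 11 cows, 5 in mild and 6 in severe negative energy balance, was measured on 1 Affymetrix bovine array each. Per the labels, total RNA was extracted with Trizol and labelled with biotin, and cows were blocked 2 weeks before calving on parity, body condition and previous yield and then allocated at random. The deposited values are log2 values made with RMA, which corrects background, normalizes arrays by quantiles and summarises probes into probe sets, per the submitters' processing notes. The log2 scale was read from the deposited values, which run between about 2.63 and 14.6. The RMA version, the software and any filter are not given in the sources used here. Quantile normalization gives all arrays nearly the same distribution, so a change common to all transcripts cannot be seen in these values. All arrays had a median of 6.20. An array has no read depth. The number of arrays limits the precision, and signals near 4 log2 units lie close to the floor, where differences are compressed. Signals under 5.52, the limit of the dimmest 40% of probe sets, are called dim. Of the named genes 6 were dim on average in mild cows alone and 5 in both groups.

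Of 24128 probe sets, 112 controls were left out and 24016 tested. In the platform annotation, dated 2016, 13292 of these had 1 gene symbol, 86 several and 10638 were not listed, and no gene was named from a probe set with several. Symbols were updated through Entrez gene numbers with a RefSeq gene table of the assembly ARS-UCD2.0, used only for names. It matched 13263 probe sets and renamed 0. Each of 9155 genes was represented by its probe set with the highest mean over the 11 arrays. Of 79 named genes, 24 had more than 1 probe set, and in 5 of these another probe set had the opposite sign, with 0 of those at an unadjusted p under 0.05.

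Severe was compared with mild by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. All adjusted p-values of single genes and of camera come from limma. In 30 lists of genes fixed before the data were examined, as were the tests, the alternatives and the rule for named genes, 29 had at least 5 measured members and were tested. Camera used its preset correlation of 0.01, and again a correlation estimated from the data, and fry was run beside it. Each cow's list score is the mean over members of the log2 value minus that gene's mean over all cows, and scores were compared by an exact two-sided permutation over the 462 splits of the cows. Correlations of scores used 100000 resamples over 11 cows and exact enumeration within the 6 severe cows. Named genes are the 12 with the largest change past the threshold in each direction, filled up by the smallest unadjusted p where fewer passed, and in each list up to 4 members past the threshold, or the 2 with the smallest p where none passed. Other genes are named where a list held few members past the threshold adjusted over the list alone, and those were chosen after their values were seen.

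The procedure was tested on simulated data with independent noise. For limma these had the spread of the real probe sets, and the changed probe sets were drawn at random. Over 24016 probe sets limma called 44% of changes of 0.5 log2 units, 90% of changes of 1, 98% of changes of 2 and 100% of changes of 3, with 13 false among 179 calls. A simulated shift of 1 log2 unit in the interferon list was called by camera, and 0 of the other 28 lists were. The noise for lists had the same SD for every gene and no correlation between genes. In the real arrays the estimated correlation within the interferon list was 0.58. The simulation therefore cannot tell how often camera with its preset correlation calls lists falsely here.

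Alternatives were a filter on the dimmest 40% of probe sets, which kept 14410, a second quantile normalization, a shift to 1 common median, eBayes with trend and robust settings, array weights, the epithelial or the neutrophil score as a covariate, each cow left out, other thresholds, 1 probe set per gene, the mean over all probe sets of a gene and the median over the members of a list. The omission of the arrays farthest from the median array, mild 2 and severe 5, and the mean 3' minus 5' difference as a covariate were added after seeing the data. Those arrays did not stand apart, as their mean distances were 0.227 and 0.236 and that of severe 2 was 0.226. The blocks of the cows are not given per animal in the sources used here and entered no test, and no batch or scan date is given there. Replicate numbers follow the order of the samples and only name the cows. Python 3.11.15 with matplotlib 3.10.9 drew the figures.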

Results

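Uterine endometrium, the mucosal lining of the womb, was collected at slaughter from 11 multiparous Holstein-Friesian dairy cows 14 ± 0.4 days after calving. RNA from each cow was measured on 1 Affymetrix bovine expression array. A cow in negative energy balance spends more energy, much of it on milk, than it takes in with feed. Cows were allocated at random to 1 of 2 regimes that began on day 2 after calving. The mild group (n = 5) ate grass silage without restriction and 8 kg of concentrate a day and was milked 1 time a day. The severe group (n = 6) received 25 kg of silage and 4 kg of concentrate a day and was milked 3 times a day. The cows had a mean parity of 4.7 and a previous lactation yield of 6477 ± 354 kg, errors as the labels give them. The deposited table held RMA log2 values of 24128 probe sets, of which 24016 were not array controls. All arrays had a median of 6.20, and correlations between arrays ran from 0.948 to 0.991. The mean 3' minus 5' difference of the control transcripts, a sign of RNA quality, was 0.56 ± 0.07 (SD, n = 5) in mild cows and 0.59 ± 0.14 (SD, n = 6) in severe cows (exact two-sided permutation p = 0.643).

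The design asks which transcripts of the endometrium differ between cows in mild and in severe negative energy balance. Single genes with large differences follow, though none passed the test across all probe sets. CXCL5, a chemokine that attracts neutrophils, averaged 10.99 ± 1.11 (SD, n = 6) in severe cows and 7.11 ± 1.58 (SD, n = 5) in mild cows, a log2 difference of 3.89, or 3.15 without mild 2 and severe 5. MMP1, an interstitial collagenase, averaged 10.82 ± 2.34 against 5.97 ± 1.42, and mild 1 and mild 2 lay at 4.91 and 4.43, near the floor of the array, so no fold is given. Its log2 difference of 4.85, not exact for the same reason, was 5.69 without severe 1 and 3.97 without mild 2 and severe 5. SAA3, an acute phase protein made by epithelia, averaged 13.13 ± 0.39 against 11.89 ± 0.52, a 2.35-fold difference. Limma called 0 of 24016 at an adjusted p under 0.05 and 0 under 0.10, the smallest adjusted p being 0.177. At an unadjusted p under 0.05 there were 3085 probe sets, 1673 higher and 1412 lower in severe cows, where 1200.8 would be expected by chance. The excess of higher ones turned after a second quantile normalization (1590 higher, 1622 lower), without mild 5 (1784 and 2010), without mild 2 and severe 5 (1292 and 1298) and with the neutrophil score as a covariate (625 and 681). In 257 probe sets (1.07%) the values of the groups did not overlap, against 0.433% by chance. Without severe 1 the count at an adjusted p under 0.05 was 16, and without severe 3 it was 2.

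The 12 genes with the smallest p among those higher in severe cows did not pass the threshold, and their values follow. TGM3, a transglutaminase that crosslinks proteins of squamous epithelia, was 7.49 ± 1.00 in severe and 4.46 ± 0.77 in mild cows, a log2 difference of 3.03 ± 0.49 (SE) with a limma adjusted p of 0.215. CXCR1, the interleukin 8 receptor of neutrophils, differed by 2.67 ± 0.45 (SE), and CFB, complement factor B, by 1.54 ± 0.27. SOD2, the mitochondrial superoxide dismutase, was 4.43-fold higher. IL1RN, the antagonist of the interleukin 1 receptor, was 2.94-fold higher, and CASP4, an inflammatory caspase, 1.91-fold. SDS, serine dehydratase, which turns serine into pyruvate and ammonia, was 7.36-fold higher at 8.92 ± 1.28 against 6.04 ± 0.60, with 1 mild cow dim. CTSL, a lysosomal cysteine protease, averaged 7.18 against 4.31. TMEM140, TRIB1 and TAPBPL had log2 differences of 0.91, 1.05 and 0.48. CXCL5 completed the 12, at a log2 difference of 3.89 ± 0.71 (SE). TGM3, CXCR1 and CTSL were dim in mild cows, with means under 5.52, the limit of the dimmest 40% of probe sets, and differences are compressed there, so the sizes of these 3 are not exact. Adjusted p in these 12 ran from 0.215 to 0.248, and for each gene 6 of 6 severe cows lay above the mean of the mild cows. Without severe 1, TGM3, CXCR1, CASP4, SDS, CTSL and TAPBPL, and MMP1 beside them, passed with adjusted p between 0.0300 and 0.0466, and CFB passed without severe 3 (adjusted p = 0.0232).

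The 12 genes with the smallest p among those lower in severe cows did not pass either. COPZ2, a coat protein of vesicles, was 8.05 ± 0.11 in severe and 8.55 ± 0.17 in mild cows, a log2 difference of -0.50 ± 0.09 (SE, limma adjusted p = 0.240). TUBA1A, an alpha tubulin, differed by -0.64 ± 0.13 and RCAN2, a regulator of calcineurin, by -1.03 ± 0.20. Among enzymes, ALDH18A1, which starts proline synthesis from glutamate, differed by -0.38, GSS, glutathione synthetase, by -0.35, DHDH by -0.57 and CYB5R3, a cytochrome b5 reductase, by -0.32. EXOSC4, a part of the RNA exosome, differed by -0.45, the zinc transporter SLC39A6 by -0.48, the dynein light chain DYNLT1 by -0.59, the co-chaperone DNAJB5 by -0.69 and MAGED1 by -0.40. The highest adjusted p among the 12 was 0.282, and for each gene 0 of 6 severe cows lay above the mild mean.

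**Figure D1:**
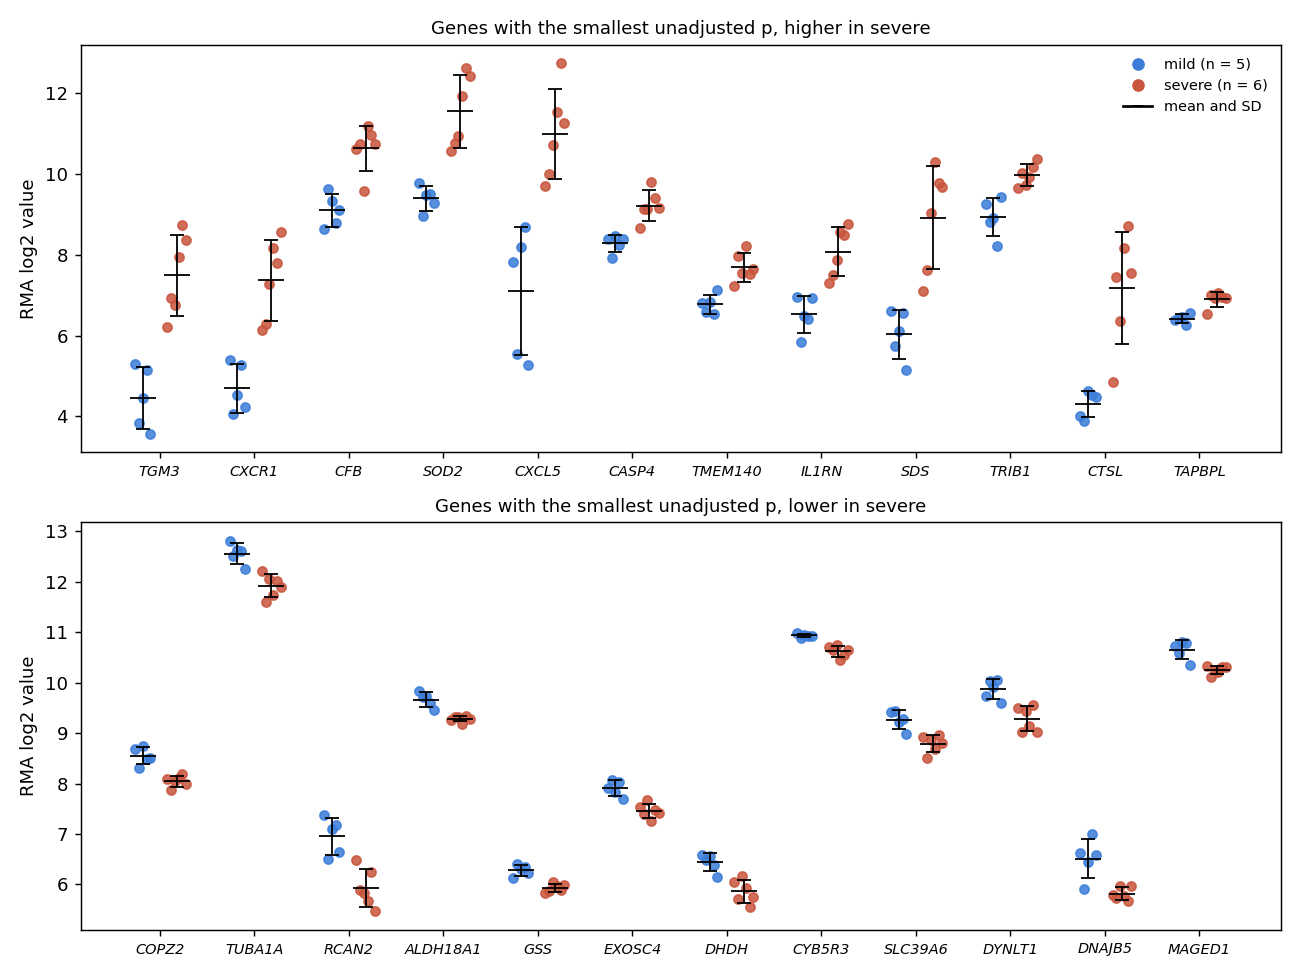
RMA log2 values (vertical axis) of the 12 genes with the smallest unadjusted p in each direction, each point 1 cow, with the mean and SD of 5 mild and 6 severe cows. SDS lies at 8.92 ± 1.28 in severe and 6.04 ± 0.60 in mild cows, and CYB5R3 in the lower panel differs by -0.32.

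Gene lists fixed before the data were examined were then compared. With its preset correlation, camera called 17 of 29 tested lists, 14 higher in severe cows, most of them of immune cells and inflammatory mediators, and 3 lower, of cell division, lipid synthesis and oxidative phosphorylation. With a correlation estimated from these arrays camera called 0 lists (smallest adjusted p = 0.355), and fry called 0 for movement in 1 direction and 11 for change in either direction. In the test that counts cows, an exact two-sided permutation of list scores over all 462 splits of the animals, 15 lists had a p under 0.05 and 0 had an adjusted p under 0.05 (smallest adjusted p = 0.0732). Without severe 1 that count was 10, and without severe 3 it was 5. The smallest unadjusted p in this test was 0.00433. The 462 splits limit how small this p can be, so no list could pass the adjustment over 29 lists on its own. With the neutrophil score as a covariate camera called 3 lists, all lower, interferon-stimulated genes at -0.36, collagens at -0.37 and oxidative phosphorylation at -0.20. These calls used the preset correlation, and the neutrophil score did not overlap between the groups, so it takes much of the group difference with it. In every list 0 members passed when adjusted over all genes, so the counts below are adjusted over the list alone.

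**Figure D2:**
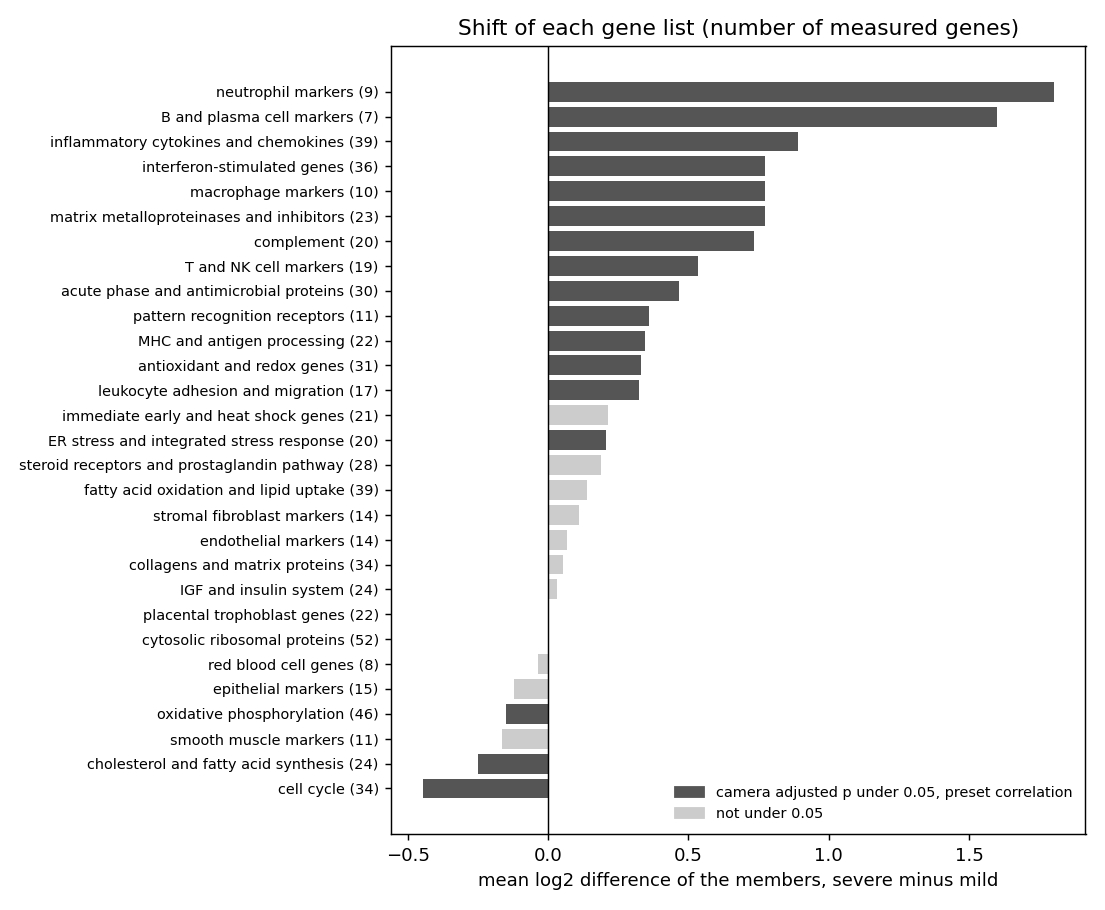
Mean log2 difference of the measured members of each list, severe minus mild (horizontal axis), with the number of measured genes in brackets. Dark bars are lists called by camera with the preset correlation, from neutrophil markers at 1.80 to cell cycle at -0.45.

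All 9 measured neutrophil markers were higher in severe cows, with a mean log2 difference of 1.80, and 6 passed adjusted over the list alone: CXCR1, S100A8, S100A12, TREM1, IL1R2 and S100A9. S100A8, a calcium-binding protein abundant in neutrophil cytosol, was 11.39 ± 1.18 (SD, n = 6) in severe and 8.15 ± 1.31 (SD, n = 5) in mild cows, or 9.45-fold higher, and CXCR1, dim in mild cows, had a log2 difference of 2.67. The neutrophil score averaged 0.82 ± 0.83 in severe and -0.98 ± 0.42 in mild cows, and 6 of 6 severe cows lay above the highest mild cow (exact p = 0.00433, adjusted p = 0.0732). Camera gave the list an adjusted p of 1.60e-08, and the adjusted p was 0.355 with an estimated correlation.

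All 39 measured inflammatory cytokines and chemokines were higher, by 0.89 on average (0.58 without mild 2 and severe 5), and 6 passed adjusted over the list alone. Those were CXCL5, IL1RN, CXCL8, PTGS2, TNFAIP6 and IL1R2, which the neutrophil list also holds. IL1RN, a natural inhibitor of interleukin 1 signalling, was among the members with the smallest p beside CXCL5, with a log2 difference of 1.55 ± 0.29 (SE). Camera called the list (adjusted p = 6.28e-11), the adjusted p was 0.377 with an estimated correlation, and the score differed with an exact p of 0.00649 (adjusted p = 0.0732), 6 of 6 severe cows lying above the highest mild cow.

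Complement was the list with the most members past the threshold, 12 of 20 adjusted over the list alone, all higher. C3, the central component of the cascade, was 13.26 ± 0.55 against 11.55 ± 0.73, a 3.28-fold difference, and CFB was 2.91-fold higher. The list differed by 0.73 on average (camera adjusted p = 1.20e-09), with an adjusted p of 0.355 with an estimated correlation and an exact p of 0.0152 for its score (adjusted p = 0.0732). Of 36 interferon-stimulated genes 35 were higher, by 0.77 on average, and 2 passed adjusted over the list alone. SAMD9, an antiviral protein, averaged 6.88 against 5.18, a dim signal in mild cows, and LGALS3BP, a secreted glycoprotein, was 1.61-fold higher. Camera called the list (adjusted p = 6.60e-11), the adjusted p was 0.377 with an estimated correlation, and the exact p of its score was 0.0346 (adjusted p = 0.0773). Severe 4 had the highest interferon score, 1.62, and the difference without that cow was 0.52.

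Acute phase and antimicrobial proteins differed by 0.47 on average and 0.14 in the median, with 20 of 30 higher, and by 1.01 over the 12 members left without dim probe sets. SAA3 passed adjusted over the list alone, and CP, the copper carrier ceruloplasmin, had a log2 difference of 1.20 ± 0.33 (SE), or 0.77 without mild 2 and severe 5. The other CP probe sets were at 0.72 ± 0.48 and 0.57 ± 0.50 (SE). Camera gave the list an adjusted p of 0.00263, against an adjusted p of 0.380 with an estimated correlation, and its score had an exact p of 0.0108 (adjusted p = 0.0732). Without mild 2 and severe 5, the arrays farthest from the median array, the camera adjusted p was 0.0551. All 11 pattern recognition receptors were higher, by 0.36 on average (camera adjusted p = 0.000552), or an adjusted p of 0.377 with an estimated correlation, and the exact p of the score was 0.0216 (adjusted p = 0.0773). TLR4, the sensor of bacterial lipopolysaccharide, was 1.69-fold higher and TLR6, which pairs with TLR2, 1.58-fold, the 2 members that passed adjusted over the list alone.

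Camera called the marker lists of B and plasma cells, T and NK cells, and macrophages higher too (adjusted p = 8.09e-05, 2.87e-06 and 0.000484), and adjusted p was 0.377, 0.377 and 0.380 with an estimated correlation. B and plasma cell markers differed by 1.60 on average, and 6 of 7 passed adjusted over the list alone. JCHAIN, which joins polymeric antibodies, had a log2 difference of 1.80 (1.18 with array weights) and IGHM, the heavy chain of IgM, one of 2.35 (2.97 without severe 1 and 1.71 without mild 2 and severe 5). T and NK cell markers differed by 0.53, and 10 of 19 passed adjusted over the list alone. ZAP70, a kinase of T cell receptor signalling, was 2.15-fold and PRF1, perforin, dim in 2 mild cows, 1.98-fold higher. All 10 macrophage markers were higher, by 0.77, but 0 passed. C1QA and C1QB, complement subunits made by macrophages that the complement list also holds, had log2 differences of 1.20 ± 0.43 and 1.20 ± 0.44 (SE). In the order above, the exact p of the scores was 0.0303, 0.0325 and 0.106. Without mild 2 and severe 5 macrophage markers were at 0.46 (camera adjusted p = 0.0551).

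The MHC and antigen processing list differed by 0.35 (camera adjusted p = 0.000354), with an adjusted p of 0.380 with an estimated correlation and an exact p of 0.275 for its score. B2M, the light chain of MHC class I, differed by 0.55 ± 0.20 (SE) and BOLA-DOA, a class II chain, by 0.95 ± 0.38 (0.60 without mild 2 and severe 5), and 0 of 22 members passed. Some class II DQ probe sets were high in some cows and near the floor in others of both groups, and the mean difference of this list was 0.17 without severe 5, 0.52 without severe 1 and 0.17 with array weights. Leukocyte adhesion and migration genes differed by 0.32 (camera adjusted p = 0.00415, and an adjusted p of 0.380 with an estimated correlation), with an exact p of 0.0866 for the score and 0 of 17 past the threshold. Without mild 2 and severe 5 the difference was 0.17 (camera adjusted p = 0.145), and that of the MHC list 0.14 (camera adjusted p = 0.0569). The chemokine CXCL12 differed by 0.49 and the integrin chain ITGB2 by 0.69. Mast cell markers had 4 measured members, too few for a list test. TPSB2, a tryptase, was the 1 that passed adjusted over the list alone, with a log2 difference of -0.39 ± 0.10 (SE), and FCER1A, a chain of the IgE receptor, differed by 0.86.

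Of 23 matrix metalloproteinases and inhibitors 15 were higher and 8 lower in severe cows, the mean difference being 0.77 and the median 0.17. Adjusted over the list alone 5 of them passed, all higher: MMP1, MMP3, MMP13, PLAU and PLAUR. MMP3, stromelysin, averaged 11.51 ± 1.57 (SD, n = 6) against 7.69 ± 1.78 (SD, n = 5), and mild 2 lay at 4.97, a dim signal. Its log2 difference of 3.81 was 3.13 without mild 2 and 2.74 without mild 2 and severe 5. Camera called the list (adjusted p = 0.00180), the adjusted p was 0.377 with an estimated correlation, and the exact p of the score was 0.0152 (adjusted p = 0.0732). Without mild 2 and severe 5 this list was at 0.51 (camera adjusted p = 0.0718). Of 34 collagens and matrix proteins 17 were higher and 17 lower, the mean being 0.05 (-0.04 without mild 2) and the median -0.01 (camera adjusted p = 0.516). THBS1, thrombospondin, differed by 0.48 ± 0.20 (SE), its other probe sets being at 0.52, 0.28, 0.16, -0.08 and -0.20. FBN1, fibrillin, differed by 0.31 ± 0.14 (SE), or 0.19 without mild 2. With the neutrophil score as a covariate metalloproteinases were at -0.15 (camera adjusted p = 0.395) and collagens were called lower at -0.37 (camera adjusted p = 8.58e-05), both with the preset correlation. That score did not overlap between the groups, so the covariate takes much of the group difference with it, and these values are not read as effects of the regime.

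**Figure D3:**
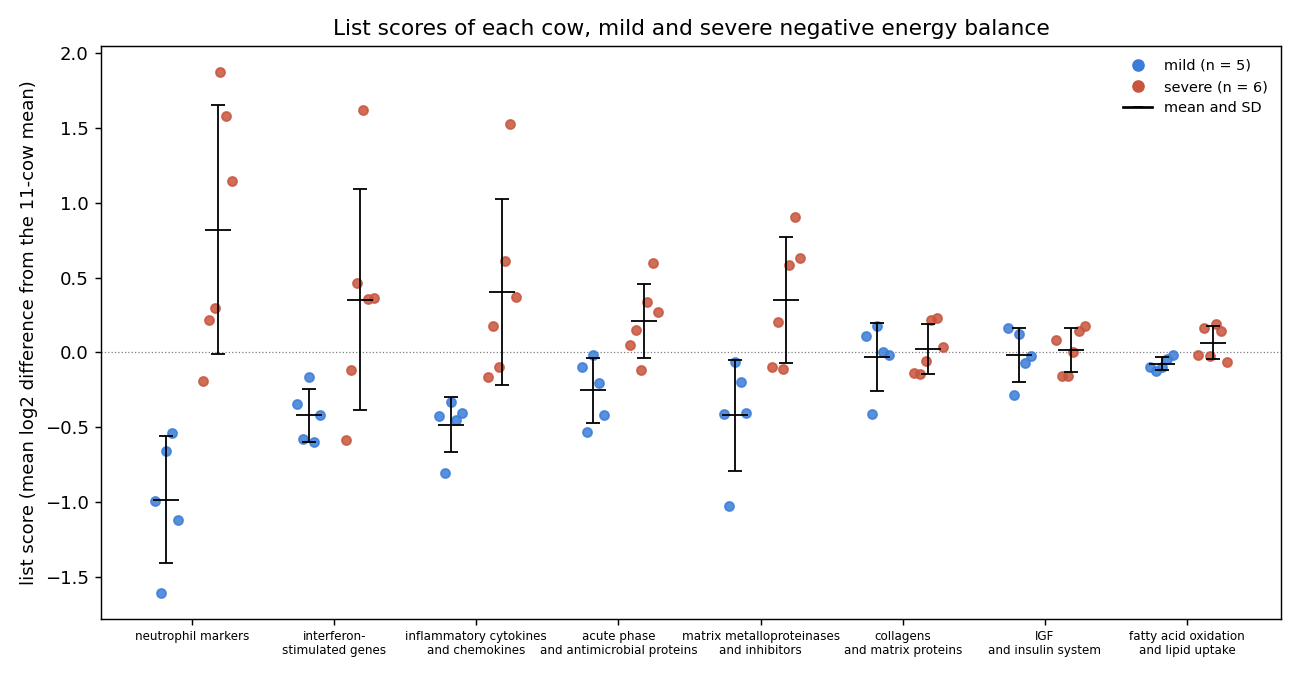
List score of each cow (vertical axis, mean log2 difference from the mean of the 11 cows) for 8 lists, with the mean and SD of 5 mild and 6 severe cows. The neutrophil score averages 0.82 in severe and -0.98 in mild cows without overlap, and the score of collagens and matrix proteins 0.02 and -0.03.

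Markers of the cells that build the endometrium were not called. Epithelial markers differed by -0.12 (camera adjusted p = 0.408), with CLDN10 and CLDN7, both tight junction claudins, at -0.997 ± 0.42 and -0.42 ± 0.21 (SE). Without severe 5 the mean difference of the epithelial list turned to 0.05, and CLDN7 was at -0.27. CLDN10 was at -0.55 without mild 2 and severe 5. Stromal fibroblast markers differed by 0.11 (camera adjusted p = 0.131), or 0.07 without severe 4, and 2 passed adjusted over the list alone in opposite directions, PDGFRA, a growth factor receptor, at 0.97 and HOXA10, a regulator of uterine identity, at -0.71. Endothelial markers differed by 0.07 (camera adjusted p = 0.337), or 0.01 without mild 2, with CDH5 at 0.24 (0.15 without mild 4) and KDR averaging 3.95 over all cows. Another CDH5 probe set was at -0.01. Smooth muscle markers differed by -0.16 (camera adjusted p = 0.337), or -0.00136 without severe 6, with TAGLN at -0.44 (-0.24 without severe 2) and ACTA2 at -0.28 (-0.16 without severe 6). Red blood cell genes differed by -0.03 (camera adjusted p = 0.530), or 0.00521 without mild 1, and HBB and HBA averaged 4.07 and 3.88 over all cows. Placental trophoblast genes differed by 0.00404 (camera adjusted p = 0.965), or -0.00665 without mild 5, with PAG17 averaging 3.73 and PRP4 3.47. KDR, HBB, HBA, PAG17 and PRP4 all lay near the floor of the array, so their differences (-0.24, -0.23, -0.11, -0.15 and -0.13) are not read as differences of these cells. None of these 6 scores had an exact p under 0.05, the smallest being 0.234 for stromal fibroblasts.

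The IGF and insulin system was not called by camera (mean 0.03, or -0.03 without mild 2, camera adjusted p = 0.400), though fry called it for change in either direction (fry adjusted p = 0.0198). In this list 1 of 24 members passed adjusted over the list alone. That was IGFBP1, a binding protein that limits access of IGF to its receptor, which was 6.02 ± 0.63 (SD, n = 6) in severe and 4.82 ± 0.35 (SD, n = 5) in mild cows, where its signal was dim. GHR, the growth hormone receptor, had a log2 difference of -0.70 ± 0.23 (SE). Fatty acid oxidation and lipid uptake was not called by camera (mean 0.14, adjusted p = 0.367), and its score had an exact p of 0.0346 (adjusted p = 0.0773). CD36, a fatty acid transporter, was 2.88-fold higher and ANGPTL4, an inhibitor of lipoprotein lipase, 1.67-fold, and 0 of 39 members passed. Cholesterol and fatty acid synthesis differed by -0.25 (camera adjusted p = 0.000323, and an adjusted p of 0.377 with an estimated correlation), with 18 of 24 members lower and an exact p of 0.0455 for the score, and by -0.16 without mild 2 and severe 5. MSMO1, an enzyme of sterol synthesis, differed by -0.51 ± 0.16 and FASN, fatty acid synthase, by -0.60 ± 0.20 (SE). Of 46 oxidative phosphorylation genes 45 were lower, by -0.15 on average (camera adjusted p = 1.60e-08, and an adjusted p of 0.377 with an estimated correlation), with an exact p of 0.0455 for the score. ATP5MC1, a subunit of ATP synthase, differed by -0.40 ± 0.13 and UQCRQ, of complex III, by -0.28 ± 0.09.

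Cell cycle genes were lower in 32 of 34 cases, by -0.45 on average (camera adjusted p = 3.16e-05, and an adjusted p of 0.464 with an estimated correlation), with an exact p of 0.182 for the score. TYMS, thymidylate synthase, differed by -0.46 ± 0.15 (SE) and ZWINT, a kinetochore protein, by -0.87 ± 0.29. Mild 2 had the highest cell cycle score, 0.95, and the mean difference of the list was -0.27 without that cow. The ER stress and integrated stress response list differed by 0.21 (camera adjusted p = 0.00204, and an adjusted p of 0.377 with an estimated correlation), with an exact p of 0.0628 for the score. Without mild 2 and severe 5 it was at 0.12 (camera adjusted p = 0.0899). ATF3, a stress-induced transcription factor, was 2.81-fold higher and passed adjusted over the list alone, and PSAT1, an enzyme of serine synthesis, was at -1.41 ± 0.46. Antioxidant and redox genes differed by 0.33 (camera adjusted p = 0.0171, and an adjusted p of 0.377 with an estimated correlation), with an exact p of 0.0152 for the score (adjusted p = 0.0732). They were at 0.25 without mild 2 and severe 5 (camera adjusted p = 0.0877). SOD2, SRXN1, which reactivates peroxiredoxins, and the metallothionein MT1A passed adjusted over the list alone, SRXN1, dim in mild cows, at 0.57 ± 0.15. Immediate early and heat shock genes were not called by camera (mean 0.21, camera adjusted p = 0.0956), though fry called them for change in either direction (fry adjusted p = 0.0198). The exact p of their score was 0.0195 (adjusted p = 0.0773), with EGR1 at 0.87 and JUNB at 0.66 (0.43 without mild 2 and severe 5). The steroid receptor and prostaglandin list was not called (mean 0.19, camera adjusted p = 0.337), though the exact p of its score was 0.0260 (adjusted p = 0.0773). PTGS2, the inducible cyclooxygenase, was 4.28-fold and PTGES, prostaglandin E synthase, 1.79-fold higher, and 0 of 28 members passed in that list. Cytosolic ribosomal proteins differed by 0.000931 (camera adjusted p = 0.894), or -0.05 without mild 5, with RPS28 at 0.15 and RPL31 at 0.10 (0.04 without mild 5).

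Cows with a high neutrophil score also had a high protease score. Over the 11 cows the neutrophil score correlated with matrix metalloproteinases and inhibitors at a Pearson r of 0.941 (permutation p = 6.00e-05, adjusted over 3 relations 0.000180) and a Spearman rho of 0.873 (permutation p = 0.000790, adjusted 0.00237). With interferon-stimulated genes r was 0.841 (permutation p = 0.000320, adjusted 0.000480) and rho 0.745 (permutation p = 0.0112, adjusted 0.0168). With epithelial markers r was -0.342 (permutation p = 0.313) and rho -0.255 (permutation p = 0.452). Without severe 4 and severe 5, the cows farthest from the median neutrophil score, r was 0.927 for metalloproteinases, 0.760 for interferon-stimulated genes and -0.311 for epithelial markers. Within the 6 severe cows r was 0.887 for metalloproteinases (exact permutation p = 0.0444, adjusted 0.0667) and 0.821 for interferon-stimulated genes (exact permutation p = 0.0278, adjusted 0.0667). By rank, rho within the severe cows was 0.657 (exact permutation p = 0.175) and 0.771 (exact permutation p = 0.103). After the group means were subtracted r was 0.878 (permutation p = 0.000480) and 0.761 (permutation p = 0.00310).

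**Figure D4:**
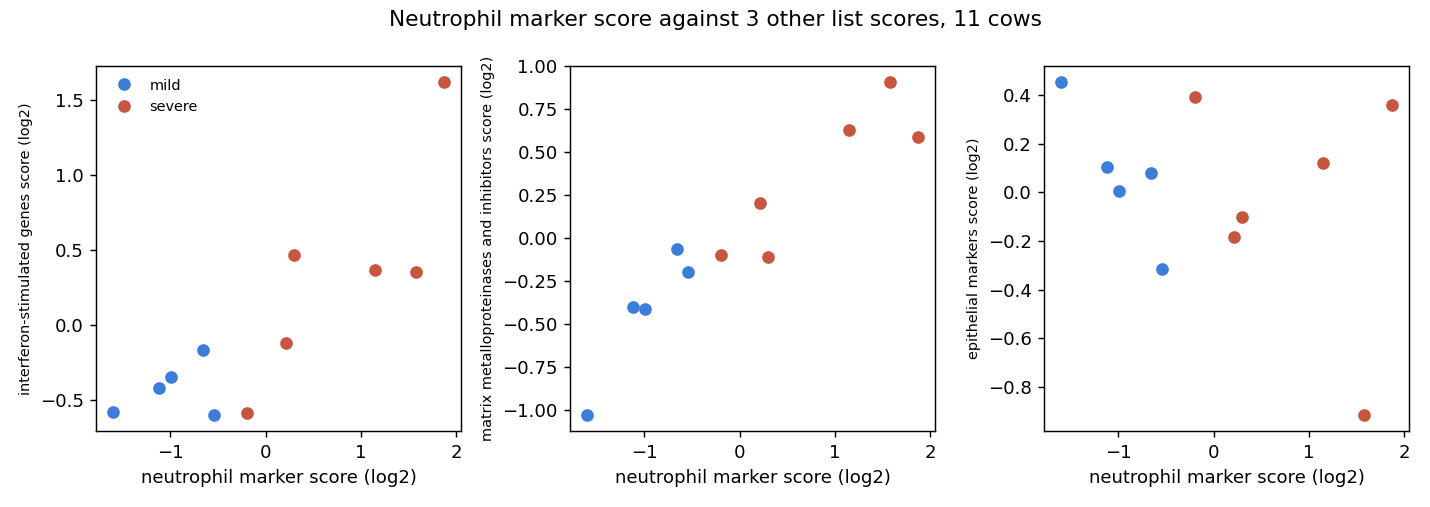
Neutrophil marker score (horizontal axis, log2) against the scores of interferon-stimulated genes, matrix metalloproteinases and inhibitors, and epithelial markers (vertical axes, log2), each point 1 cow, 5 mild and 6 severe. The first and the second panel rise together (r = 0.841 and 0.941) and the epithelial panel does not (r = -0.342).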

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

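The tests of cell type share and of MHC class II were chosen after the results they measure were seen, as were the alternatives with the RNA quality covariate. A cow was singled out where its gap to the nearest other cow of its group was larger than Dixon's 95% value allows. This happened in 12 of 216 group comparisons of list scores and named genes, where chance would give 10.8.

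Mild 2 had the lowest inflammatory cytokine score of its group (-0.80, the next cow -0.45), the lowest CP (6.95, next 8.25) and the highest TYMS (8.23, next 7.73). Mild 3 had the highest B and plasma cell score of the mild cows (0.48, next -1.02) and the highest IGHM (12.002, next 9.48). Mild 5 had the lowest oxidative phosphorylation score (-0.11, next 0.12) and the lowest ATP5MC1 (8.74, next 9.20). In mild 1 HBB, near the floor in all cows, was 4.57, next 4.14. Among severe cows, SAA3 was highest in severe 5 (13.87, next 13.16), CFB was lowest in severe 3 (9.59, next 10.62), and severe 1 had the lowest TAPBPL (6.54, next 6.94) and the lowest placental trophoblast score (-0.072, next 0.0026).

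Whether other splits of the 11 cows give as much was counted in 100 of the 462 splits, the real one included. At an unadjusted p under 0.05, 3 of the 100 splits gave at least as many probe sets as the real 3085. The highest of the others was 3882 and their median 905. The split with 3882 set severe cows alone against all mild cows and 1 severe cow. It is the real grouping with 1 cow moved, so it carries much of any real group difference. Counts this high were uncommon, and fewer than the limit set beforehand for reading them as chance, but 3 of 100 does not exclude it. For the number of lists called by camera, 17 of the 100 splits gave at least the real 17. The highest of the others was 21 and their median 10. The split with 21 set severe cows and 1 mild cow against the other cows, so it kept most of the real grouping. Several others that reached 17 did so too, and some mixed the groups more evenly. This count therefore does not show what chance alone gives, and chance cannot be excluded. At an adjusted p under 0.05 the real count was 0, which all 100 splits reached, the highest other being 26, and 1 split called any probe set. That was the split with 3882 probe sets, the real grouping with 1 cow moved, so its 26 calls are not read as calls by chance.

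Neutrophil markers were higher in severe cows in each of 9 members, the abundant S100A8 averaging 11.39 against 8.15. A lower share of the cells that build the tissue would raise every leukocyte type alike if all marker lists responded alike. The neutrophil difference exceeded that of T and NK cells by 1.27 and that of macrophages by 1.03 (exact p = 0.0152 and 0.0173, adjusted over 3 types 0.0260 for both). It did not clearly exceed that of B and plasma cells (0.20, exact p = 0.643). These values do not decide the question, because lists may differ in how their signals respond, low ones being compressed. The mean 3' minus 5' difference was alike in mild and severe cows (0.56 and 0.59, exact two-sided permutation p = 0.643). As a covariate it could therefore hardly change the score difference, which was 1.92 ± 0.36 (SE) with it and 1.80 without it. RNA quality that this measure misses stays open. A single cow as the cause is argued against, since 6 of 6 severe cows lay above the highest mild cow. With that separation the highest unadjusted exact p over the 11 omissions was 0.0143. More neutrophils in the tissue, a lower share of the other cells, more of these transcripts per cell and uterine infection, which is not given in the sources used here, stay open. Counts of neutrophils and other cells in sections, with bacterial culture of the same uteri, would separate them.

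Interferon-stimulated genes were higher in severe cows in 35 of 36 members. With the 3' minus 5' difference as a covariate the score difference was 0.87 ± 0.30 (SE), against 0.77 without it. That covariate was alike in the groups and could hardly change the difference, so RNA quality is not decided here. Dependence on single cows stays open: the exact p was 0.0905 without mild 4, in a test with fewer splits where the difference stayed about as large at 0.73, and without severe 4 the difference was 0.52. An effect of the regime on interferon signalling therefore stays an untested hypothesis, which interferon levels in more cows of both regimes would test.

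MHC class II DQ probe sets were high in some cows and near the floor in others, while BOLA-DRA ran smoothly from 9.72 to 12.23. For BOLA-DQB1, 1 probe set was above the array median of 6.20 in 2 of 5 mild and 6 of 6 severe cows and another in 5 of 5 and 4 of 6. The SD over cows of the difference between these probe sets was 3.68, against 0.47 for a pair of BOLA-DRB3 probe sets, which is consistent with alleles that differ in how well they match the probes. For the first probe set an effect of energy balance cannot be told apart from that (Fisher's exact two-sided p = 0.0606), because all severe cows were above the median there. The other BOLA-DQB1 probe set leaned the other way. The genotypes of the cows were not analysed here.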

How the results depend on the processing

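No paired analysis was possible because the labels mention blocks of cows but do not assign animals to them, and replicate numbers only name the cows. Leaving out mild 2 and severe 5, and RNA quality as a covariate, were chosen after seeing the data. The count of 0 probe sets at an adjusted p under 0.05 stood at 0 under the dim filter, both rescalings, trend and robust settings, array weights, each covariate, 1 probe set per gene and without mild 2 and severe 5. It ran from 0 to 16 as cows were left out, being 16 without severe 1 and 2 without severe 3, and 341 probe sets had an unadjusted p under 0.01 with a 1.5-fold difference. The count at an unadjusted p under 0.05 ran from 2213 to 3794 as cows were left out and was 1306 with the neutrophil score as a covariate. The shift to a common median had little to move (3092 probe sets).

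Camera called between 17 and 20 lists as cows were left out, 0 with an estimated correlation, 3 with the neutrophil score as a covariate and 10 without mild 2 and severe 5. With an estimated correlation the mean differences are by construction those of the preset one, 1.80 for neutrophil markers, 0.77 for macrophage markers, 0.53 for T and NK cell markers, 1.60 for B and plasma cell markers, 0.77 for interferon-stimulated genes, 0.89 for cytokines, 0.47 for acute phase proteins, 0.36 for pattern receptors, 0.32 for leukocyte adhesion, 0.73 for complement, 0.35 for MHC, 0.77 for metalloproteinases, -0.45 for cell cycle, -0.25 for lipid synthesis, 0.21 for ER stress, 0.33 for antioxidant genes and -0.15 for oxidative phosphorylation, and each lost its call (adjusted p from 0.355 to 0.464), because correlated members count as fewer genes. Without mild 2 and severe 5 calls were lost at 0.46 for macrophage markers, 0.32 for acute phase proteins, 0.17 for leukocyte adhesion, 0.14 for MHC, 0.51 for metalloproteinases, 0.12 for ER stress and 0.25 for antioxidant genes, the lowest adjusted p being 0.0551 and the highest 0.145, with fewer cows. Antioxidant genes lost the call with array weights (0.30, adjusted p = 0.0562).

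With the neutrophil score as a covariate the mean difference turned to -0.45 for macrophage markers, -0.30 for B and plasma cell markers, -0.36 for interferon-stimulated genes, -0.10 for cytokines, -0.012 for acute phase proteins, -0.18 for leukocyte adhesion, -0.51 for MHC, -0.15 for metalloproteinases, -0.37 for collagens, -0.16 for the IGF system, -0.078 for ER stress and -0.022 for antioxidant genes. Calls were lost at 0.27 for T and NK cell markers, -0.039 for pattern receptors, 0.047 for complement, -0.083 for cell cycle and -0.20 for lipid synthesis, where camera's direction for pattern receptors stayed upward. The neutrophil score did not overlap between the groups, so the covariate takes much of the group difference with it. The lists called in that fit were interferon-stimulated genes, collagens and oxidative phosphorylation, all lower. Among named genes the sign turned, all in that fit, to -0.042 for B2M, -0.42 for BOLA-DOA, -0.26 for C1QA, -0.30 for C1QB, 0.19 for CLDN10, -0.21 for CP, 0.046 for FASN, -0.083 for FBN1, -0.14 for FCER1A, -0.43 for IGHM, -0.11 for ITGB2, -0.24 for JCHAIN, -0.13 for JUNB, -0.064 for LGALS3BP, -0.071 for PDGFRA and 0.0025 for TYMS. Of 1574 values of named genes these 16 turned their sign, 8 passed the threshold as a cow was left out, and 1550 kept both their sign and their side of the threshold.

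Collagens and the IGF system lay near 0 and changed sign elsewhere too. For collagens camera pointed downward after a second quantile normalization (mean 0.0014) and with array weights (-0.022), the mean and score were -0.084 without mild 2 and severe 5, the score was -0.0046 with the mean of all probe sets, and the range over cows left out was -0.043 to 0.10. For the IGF system the score was -0.026 without dim probe sets, the mean was -0.0086 with array weights, and the mean and score were -0.059 without mild 2 and severe 5. Its range over cows left out was -0.033 to 0.078. Both had their lowest value without mild 2. Over all 29 lists the scores of 6 changed sign as a cow was left out, these and the epithelial (0.052 without severe 5), red blood cell, trophoblast and ribosomal lists. The causes were not tested.

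The number of list scores with an adjusted exact p under 0.05 ran from 0 to 10 as cows were left out, being 10 without severe 1 and 5 without severe 3. The score differences ran from 1.59 to 2.01 for neutrophil markers, 0.52 to 0.96 for interferon-stimulated genes, 0.66 to 1.00 for cytokines, 0.62 to 0.86 for metalloproteinases, 0.39 to 0.53 for acute phase proteins, 0.66 to 0.85 for complement, 0.44 to 0.62 for T and NK cells, 1.33 to 1.94 for B and plasma cells, 0.31 to 0.42 for pattern receptors and 0.28 to 0.39 for antioxidant genes. With the median over the members the score differed by 0.58 for cytokines, 0.17 for acute phase proteins, 0.34 for metalloproteinases, 0.21 for pattern receptors, 0.18 for antioxidant genes and 0.050 for fatty acid oxidation. The 3 correlations kept their sign and side of 0.05 without the 2 farthest cows and after the group means were subtracted. Within the 6 severe cows the adjusted exact permutation p of r was 0.0667 for metalloproteinases and for interferon-stimulated genes.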

Other observations

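The genes outside the lists named here were picked after their values were seen, from those with large differences and an unadjusted p under 0.01, and none passed limma's adjusted threshold. Among these, STC1, the secreted glycoprotein stanniocalcin 1, was 9.20 ± 1.34 (SD, n = 6) in severe and 6.52 ± 0.64 (SD, n = 5) in mild cows, or 6.40-fold higher (adjusted p = 0.269). SPINK1, a trypsin inhibitor, was 4.77-fold higher and CHI3L1, a chitinase-like protein of inflamed tissue, 4.72-fold. SRGN, a granule proteoglycan, was 3.12-fold, CD53, a tetraspanin of leukocytes, 3.04-fold, and BCL2A1 3.28-fold higher. CD69, an activation marker, averaged 5.84 against 4.46, a dim signal in mild cows. NFKBIZ, an atypical regulator of NF-kappaB, was 2.81-fold, CEBPD, an acute phase transcription factor, 2.38-fold and PFKFB3, which drives glycolysis, 2.66-fold higher. The epithelial growth factor NRG1 differed by 1.37 ± 0.36 (SE).

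Lower in severe cows were PTHLH, parathyroid hormone-like hormone, at 5.54 ± 0.75 against 7.30 ± 0.90 (log2 difference -1.77 ± 0.44, SE, adjusted p = 0.285), MPPED2 at -1.50 and TAC3, the precursor of neurokinin B, at -1.30. SDC2, a heparan sulphate proteoglycan, differed by -0.998, SPDEF, a transcription factor of secretory epithelium, by -0.997, MFSD2A, a transporter of lysophospholipids, by -0.89, and CPE, a carboxypeptidase that processes peptide hormones, by -0.75. MPPED2, TAC3 and SPDEF were dim in severe cows, with means of 5.47, 4.50 and 5.10, so the sizes of their differences are not exact.

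Severe cows looked more spread than mild cows on the immune scores, and a hypothesis was that the severe group varies more over the whole array. The median log2 ratio of the within-group variances, severe over mild, was 0.0145 (permutation p = 0.894 over the 462 splits of group-centred values), and 50.3% of probe sets varied more in severe cows, so this test did not separate the hypothesis from equal spread.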
